A study of Mus musculus with 4 samples.

How the data were processed

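RNA was extracted from cultured mouse erythroblasts and made into libraries with commercial kits, per the labels' protocols. The labels describe 4 samples in 4 groups, 1 per group. They do not say whether a sample was pooled from several cultures. Cufflinks 2.0.2, Cuffdiff, FastQC 0.10.1 and the mm9 mouse genome are named in the submitters' processing notes. The aligner and the gene annotation are not given in the sources used here.

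The authors deposited 1 table of pairwise comparisons, and its columns have the layout of Cuffdiff output. Per the file headers, each row of the deposited table holds a gene, its locus, the names of 2 libraries, a value for each, a log2 ratio, a test statistic, a p-value, a q-value and a mark for significance. The authors' values per library were read as FPKM (fragments per kilobase of transcript, scaled to the library's fragments), since the labels name Cuffdiff, which writes that unit. The table used here has 65535 rows in 3 comparisons: 2 cover 23234 genes and the third covers 19067. No row for the maturing knockdown sample was used, so 2 of the 4 planned comparisons were made. A sample was matched to a name in the table by its label. The name of the proliferating knockdown library holds the target that its labels give and the number in its title. That title also begins like those of the control samples, and the labels do not explain the number, so the match rests on the target and the number together. Genes were marked exactly where the deposited q-value was at most 0.05. The deposited log2 ratio differed from that of the FPKM values by at most 0.000109 among tested genes. The deposited p-value matched the two-sided normal tail of the statistic within 0.001 for all tested genes. The ratio of log2 ratio to statistic therefore gave the standard error of the authors' model, with a median of 0.45 for genes at 5 FPKM or more in both libraries.

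Sizes were computed as the log2 ratio of FPKM + 1, which understates the change of low genes. A gene was measured at 1 FPKM or more in at least 1 of the 3 libraries. No test was run on these values, because each group had 1 library. The authors' calls were counted by direction, and genes with a log2 ratio of 1 or more in size were counted beside them. For 23 gene lists of 408 entries, 405 of which matched a row, the median ratio of measured members was set against 10000 random lists of the same size, matched on mean log2(FPKM + 1) in 20 bins. Gene synonyms came from a RefSeq table that was used for names only. A list needed 3 measured members and stood apart in the lowest 2.5% or the highest 2.5% of random lists, a description of these libraries. The deposited p-values of measured members were also adjusted by the Benjamini-Hochberg method over the list alone, at 0.05. Calls on a list were counted among its measured members. Rows that name several genes (90 rows) were kept as they are. Coordinates are those of the deposited table.

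Depth is not given by FPKM values. Among genes below 0.03 FPKM in both libraries, the commonest ratio of values shows what 1 fragment is worth in one library relative to another. It gave the relative depths from 1807 genes for the knockdown and 2078 for the maturing control. The absolute depth is unknown, and no counting interval was computed.

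The gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule names Setd8 and Gata2 first. It then takes the 10 highest and the 10 lowest ratios among called genes with at least 5 FPKM in 1 library of a comparison. Up to 4 called members per list follow, first in the prevailing direction and then against it, and 1 gene that the rule takes is not reported here. Members of lists without a call are given by value, and predicted genes and short RNAs are counted but not named. Members that were not called (among them Rhag, Gata1, Tal1, Kit, Cpa3, Cd68, Pcna, Mki67, Cdc6, Ube2c and Npm1) were chosen after their values were seen. Alternatives were a q-value under 0.01, a size of 1 beside the call, filters at 1 and 5 FPKM or none, pseudocounts of 0.1 and 5, and the mean in place of the median. Other scalings were centring on abundant genes, an equal upper quartile, TPM, and an equal sum without globins. The list step was tested on simulated data. In the knockdown comparison over 9611 genes, 20-gene lists shifted by 0.5 on the log2 scale stood apart in 100% of draws, and lists without a shift in 4.5%. With 10 genes and a shift of 0.25 the share was 55%. In the maturation comparison over 9611 genes, these shares were 100%, 4% and 84%. Simulated unchanged libraries (100 draws) used the standard errors of the authors' model. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.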

Results

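RNA sequencing was described for mouse extensively self-renewing erythroblasts, immature red cell precursors that can be expanded in culture. The labels gave 4 groups of 1 sample each. Cells carried a non-targeting short hairpin RNA or one against Setd8. They were proliferating or had been placed in maturation medium 6 h before RNA collection. Setd8 is the enzyme that places a single methyl group on lysine 20 of histone H4. Levels of 23234 genes in FPKM were used for 3 libraries: proliferating control, proliferating knockdown and maturing control. The maturing knockdown group was not analysed here, so the effect of the knockdown during maturation, and of maturation in knockdown cells, are not reported. At least 1 FPKM was reached by 8923 genes in the proliferating control, 9158 in the proliferating knockdown and 8981 in the maturing control. The FPKM worth of a single fragment among very low genes gave the knockdown library a depth 1.44 times, and the maturing control library a depth 1.55 times, that of the proliferating control. The ribosomal RNA precursor Rn45s stood at 190.5 FPKM in the knockdown, 2.01 times its level in the proliferating control, and at 133 FPKM in the maturing control, 1.40 times that level. With 1 library per group there was no replicate check of any difference, and the calls below are those of the authors' deposited table, made without replicates named in the labels.

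The first comparison asked what a lower Setd8 level changed in proliferating cells. Setd8 (chromosome 5, 124889938 to 124912316, mm9) stood at 25.1 FPKM in the proliferating control, 9.28 FPKM in the proliferating knockdown and 25.9 FPKM in the maturing control. The knockdown library thus held 37.0% of the control level. The authors' deposited table gave Setd8 a log2 ratio of -1.43 with an adjusted p (q) of 0.0122. Gata2, a transcription factor of early blood progenitors that the study's title names as repressed by Setd8, lies on chromosome 6 from 88148657 to 88157026. It was at 54.9 FPKM in the proliferating control, 129 FPKM in the knockdown and 29.6 FPKM in the maturing control. For the knockdown the authors' deposited table gave Gata2 a log2 ratio of 1.24 and a q of 0.0156. For maturation it was not called in the authors' deposited table, with a log2 ratio of -0.89 and a q of 0.208.

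**Figure D1:**
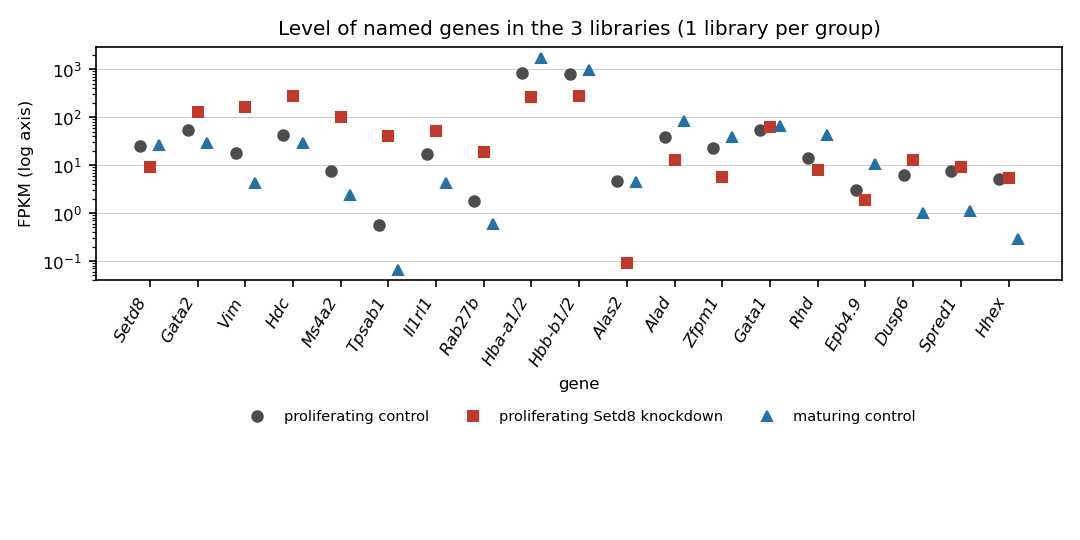
FPKM (log axis) of 19 named genes in the proliferating control, proliferating knockdown and maturing control libraries, 1 point per library with no error. Gata2, Vim, Hdc, Ms4a2 and Tpsab1 sit highest in the knockdown library and both adult globin entries sit lowest there.

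Red cell gene lists had lower medians in the knockdown. All 7 measured entries of the globin list had a lower value, with a median log2 ratio of FPKM + 1 of -1.53, below every one of 10000 random lists matched on expression. Of the 7, 4 were called lower in the authors' deposited table, and 5 were lower when adjusted over the list alone. The shared entry of the alpha-globin genes Hba-a1 and Hba-a2 went from 843 to 265 FPKM, and that of the beta-globin genes Hbb-b1 and Hbb-b2 from 798 to 279.6 FPKM. These near-identical copies share fragments, so the split between them is uncertain. The early beta-like globin Hbb-bh1 went from 12.5 to 3.65 FPKM. Of 19 genes of haem synthesis and iron handling, 17 had a lower value, at a median of -0.87, again below every random list. The authors' deposited table called 4 of the 19 lower, and 10 were lower when adjusted over the list alone. Alas2, the first enzyme of haem synthesis in red cells, went from 4.55 to 0.0900 FPKM. Alad, which acts next in the pathway, went from 38.0 to 12.9 FPKM. The ferrireductase Steap3 went from 18.4 to 7.03 FPKM.

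The 19 measured genes of the red cell membrane and skeleton had a median of -0.47, below every random list. Of these, 3 were called lower in the authors' deposited table and 5 when adjusted over the list alone. Add2, which encodes beta-adducin, went from 9.76 to 0.842 FPKM, and Spna1, the alpha-spectrin gene, from 4.84 to 0.124 FPKM. Aqp1 was listed at 0 in the knockdown and at only 0.192 FPKM in the control. Rhag, at 77.9 and 119 FPKM, had a higher value and was not called. Erythroid transcription factors had a median of -0.46 over 16 measured genes, below every random list. Only Zfpm1, the Gata1 cofactor also known as Fog1, was called lower among them in the authors' deposited table, and likewise when adjusted over the list alone. It went from 22.7 to 5.70 FPKM. Gata1 itself was at 52.8 and 61.1 FPKM and Tal1 at 40.3 and 49.0 FPKM, neither of them called.

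Several progenitor and mast cell genes were called higher in the authors' deposited table. The 12 measured genes of the progenitor and Gata2-linked list had a median of 0.62, above every random list. With no filter on low values the list had 20 members, and the median was 0.0299 at percentile 99.6. The authors' deposited table called 4 of the 12 higher and none lower, and 4 were higher adjusted over the list alone. Beside Gata2, the intermediate filament gene Vim went from 17.8 to 163 FPKM, the histidine decarboxylase gene Hdc from 42.5 to 277 FPKM and Erg from 1.78 to 6.51 FPKM. Kit, the stem cell factor receptor, was at 58.0 and 120.1 FPKM, but its test failed in the authors' deposited table. Among 11 measured mast cell and basophil markers the median was 1.10, at percentile 99.99 of random lists, and it ranged from 0.60 with a pseudocount of 5 to 2.87 over members at 5 FPKM or more. Tpsab1, Tpsb2 and Cma1 reached 5 FPKM only in the knockdown library, which raises the last value. Tpsab1 and Tpsb2 reached even 1 FPKM only there. Mcpt4 and Mitf, named after their values were seen, did likewise. The median of 1.10 therefore also rests in part on members that were measured only through their knockdown value. Of the 11 markers, 7 were called higher and 1 lower in the authors' deposited table, and the counts were the same when adjusted over the list alone. The tryptase Tpsab1 went from 0.565 to 40.4 FPKM, the tryptase Tpsb2 from 0.143 to 7.37 FPKM and the chymase Cma1 from 1.61 to 21.0 FPKM. The 2 tryptases are similar in sequence, so the split between them is uncertain. Ms4a2, the beta chain of the IgE receptor, went from 7.65 to 99.3 FPKM. Cpa3, a mast cell carboxypeptidase, was at 3.16 FPKM in the knockdown and was not called. Granzyme B (Gzmb) was the called exception, at 1.43 and 0.00592 FPKM. The 6 measured megakaryocyte and platelet markers had a median of 0.94, above every random list. With no filter on low values it was 0.0141 over 17 genes, at percentile 99.9. The authors' deposited table called 3 of the 6 higher, the same number as adjusted over the list alone. These were Rab27b, at 1.75 and 18.9 FPKM, Itga2b, at 2.54 and 7.25 FPKM, and Gp9, at 0.594 and 2.31 FPKM. Of the markers of other cells, no lymphocyte marker reached 1 FPKM. Fcgr3, at 3.59 and 10.4 FPKM, and Trf, at 0.0364 and 2.39 FPKM, were called higher in the authors' deposited table from the granulocyte and monocyte list and from the fibroblast, endothelial and hepatocyte list. Cd68 was the other measured granulocyte and monocyte marker, at 0.855 and 0.377 FPKM, and was not called. Adjusted over the list alone, Fcgr3 passed as higher and Cd68 as lower in the first list, and Trf, the 1 measured gene of the second, as higher.

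Genes of proliferation and stress had lower medians with few calls. DNA replication (26 genes, median -0.37), mitosis (25 genes, -0.36) and ribosome biogenesis (21 genes, -0.32) stood at percentiles 0.02, 0.02 and 0.2 of random lists. No gene of these 3 lists was called in the authors' deposited table, and 0 were called adjusted over the list alone. Pcna was at 123 and 109.6 FPKM and Mki67 at 29.1 and 25.1 FPKM. The 21 measured genes of the p53 target list had a median of -0.34 at percentile 0.03, with 3 called lower in the authors' deposited table and 3 adjusted over the list alone. They were Gadd45a, at 24.8 and 7.68 FPKM, Cdkn2a, at 3.21 and 0.320 FPKM, and Eda2r, at 1.14 and 0.0937 FPKM. Cdkn2a was on the fixed list but acts upstream of p53, so its lower value is not that of a p53 target. The list of unfolded protein and amino acid stress had a median of -0.53 over 14 genes, below every random list. The authors' deposited table called 3 of the 14 lower, against 4 adjusted over the list alone. Phgdh, the first enzyme of serine synthesis, went from 11.0 to 0.00434 FPKM and Trib3 from 2.53 to 0.393 FPKM. Heat shock genes (10 genes, median -0.36, percentile 0.44) held 1 gene called lower in the authors' deposited table, also adjusted over the list alone. This was Hsph1, at 24.9 and 9.54 FPKM. In the list of H4K20 methylation and Setd8 turnover (11 genes, median -0.29, percentile 1.73) Setd8 was the 1 gene called in the authors' deposited table, with 1 adjusted over the list alone. With the mean, or over members at 5 FPKM or more, this list did not stand apart.

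Growth factor and MAPK response genes had a median of 0.50 over 12 genes, at percentile 99.8. The authors' deposited table called 2 higher and 1 lower, against 5 and 1 adjusted over the list alone. Ccnd1 was at 0.192 and 1.67 FPKM and Ccnd2 at 8.75 and 1.83 FPKM. Erythropoietin and STAT5 targets had a median of 0.29 over 10 genes at percentile 99.2. Of these, 1 was called higher and 1 lower in the authors' deposited table, against 2 and 2 adjusted over the list alone. Osm was listed at 0 in the control and stood at 4.61 FPKM in the knockdown. With the mean in place of the median, neither of these 2 lists stood outside the middle 95% of random lists, and over members at 5 FPKM or more the first did not either, and with no filter on low values its median was 0.13. Glucocorticoid-induced genes (13 genes, median 0.13), other histone lysine methyltransferases (16 genes, 0.08), autophagy and late maturation (17 genes, -0.03) and interferon-stimulated genes (4 genes, 0.02) lay within that range. For the first 3 of these 4 the mean had the opposite sign of the median. The authors' deposited table called Sgk1 higher and Dusp1 lower in the first and Ube2l6, at 2.33 and 20.2 FPKM, higher in the autophagy list, and none in the others. Adjusted over the list alone, 2 glucocorticoid-induced genes were higher and 1 lower, 1 autophagy gene was higher, and 0 passed in the other 2 lists. Medians of the glucocorticoid-induced list over members at 5 FPKM or more (-0.14) and of the autophagy list on the TPM scale (0.02) had the opposite sign. Of the 20 lists with a median, 16 stood apart, 11 low and 5 high. Random lists hold unrelated genes while listed genes can vary together, so no number expected by chance is given.

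**Figure D2:**
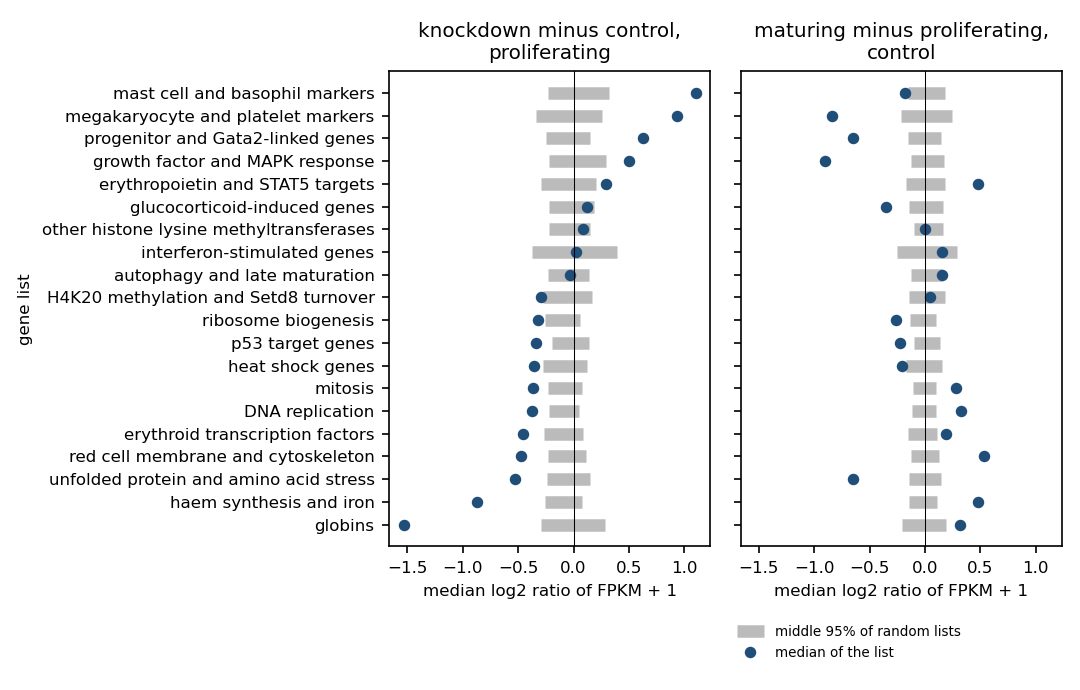
Median log2 ratio of FPKM + 1 (points) of 20 gene lists for knockdown minus control and for maturing minus proliferating, with the middle 95% of 10000 random expression-matched lists (grey bars). Globins sit at -1.53 in the knockdown panel and at 0.31 in the maturation panel, and the progenitor list at 0.62 and -0.65.

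Over all genes, the authors' deposited table called 1056 changed in the knockdown library against the control library, 678 higher and 378 lower. Among those with at least 5 FPKM in a library, the largest increases included Cited1, at 0.127 and 35.7 FPKM, Pmp22, at 0.162 and 33.6 FPKM, and the transcriptional inhibitor Id2, at 5.37 and 171 FPKM. Rab31 (0.445 and 37.0 FPKM), the amino acid transporter Slc7a8 (1.53 and 62.9 FPKM) and Dtx4 (0.0408 and 23.2 FPKM) followed. Serpinb1a, Serpinb1b and Serpinb1c reached 40.1, 37.0 and 35.8 FPKM from 0.344, 0.328 and 0.29 FPKM. These 3 neighbouring copies can share fragments, so their separate levels are uncertain. The largest decreases included Ly6e, at 76.6 and 0.0297 FPKM, S100a10, at 25.5 and 0.138 FPKM, and Cox6b2, at 15.8 and 0.1 FPKM. The similar neighbours Hemt1 and Gml were at 17.1 and 13.9 FPKM in the control and listed at 0 in the knockdown. Parvb (9.74 and 0.00462 FPKM), Cnn3 (9.09 and 0.0178 FPKM), Bex4 (180.0 and 16.1 FPKM) and Bex6 (102.1 and 9.45 FPKM) followed after Phgdh, given above. Bex4 and Bex6 are from 1 family of similar genes. By size alone, 671 genes had a log2 ratio of 1 or more, 421 higher and 250 lower. Many calls were of low genes: 559 had at least 1 FPKM in a library and 247 at least 5 FPKM. The median log2 ratio of the 4364 genes with 5 FPKM or more in every library was -0.09.

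The second comparison asked what 6 h in maturation medium, called maturation here, changed in control cells. Direct effects of the medium and maturation itself cannot be told apart in this pair. Most measured genes of the growth factor and MAPK response, among them feedback inhibitors of that pathway, were called lower in the authors' deposited table. The median over 12 measured genes was -0.90, below every random list, and it ranged from -0.38 with no filter on low values to -1.85 with a pseudocount of 0.1. The authors' deposited table called 7 of the 12 lower and none higher, against 8 and 0 adjusted over the list alone. Dusp6 went from 6.23 to 1.02 FPKM, Spred1 from 7.48 to 1.09 FPKM, Spred2 from 6.13 to 0.931 FPKM and Egr1 from 3.12 to 0.0382 FPKM. The 12 measured progenitor genes had a median of -0.65, below every random list. With no filter on low values the median was -0.0475 over 20 genes, at percentile 0.52. Of these, 3 were called lower in the authors' deposited table, against 6 adjusted over the list alone. Hhex went from 5.14 to 0.294 FPKM, Vim from 17.8 to 4.24 FPKM and Myb from 42.2 to 18.9 FPKM.

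Red cell gene lists had higher medians in the maturing control. Lower values were held by 3 of 19 membrane genes, 1 of 19 haem and iron genes and 6 of 16 erythroid transcription factors. The 19 measured membrane and skeleton genes had a median of 0.53, above every random list, with 4 called higher in the authors' deposited table and 4 adjusted over the list alone. Rhd went from 14.4 to 41.9 FPKM, Epb4.9 from 3.07 to 10.3 FPKM, the anion exchanger Slc4a1 from 0.792 to 2.34 FPKM and Aqp1 from 0.192 to 1.73 FPKM. For haem synthesis and iron the median was 0.48 over 19 genes, above every random list. In the authors' deposited table Slc25a37, the iron importer of mitochondria, was the 1 gene called, against 3 higher adjusted over the list alone. It went from 3.54 to 10.2 FPKM. All 7 entries of the globin list had a higher value, with a median of 0.31 at percentile 99.7. None was called in the authors' deposited table, and 0 were called adjusted over the list alone. The shared entry of Hba-a1 and Hba-a2 was at 843 and 1747 FPKM. Erythroid transcription factors had a median of 0.19 over 16 genes at percentile 99.8, with 0 called in the authors' deposited table and 0 adjusted over the list alone. With the mean, or with no filter on low values, they did not stand apart. Erythropoietin and STAT5 targets had a median of 0.48 over 10 genes, above every random list. Cish, at 4.80 and 14.8 FPKM, and Fam132b, the erythroferrone gene, at 0.627 and 4.11 FPKM, were the 2 called higher in the authors' deposited table, against 3 adjusted over the list alone.

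Several markers of related lineages were called lower in the authors' deposited table. The 11 measured mast cell and basophil markers had a median of -0.18 at percentile 1.26, with 4 called lower in the authors' deposited table and 4 adjusted over the list alone. With a pseudocount of 5 this list did not stand apart, and with one of 0.1 its median was -0.62. Its members Tpsab1, Tpsb2, Mcpt4 and Mitf were below 1 FPKM in both libraries of this comparison. Il1rl1 went from 16.7 to 4.19 FPKM, Ms4a2 from 7.65 to 2.42 FPKM and Tpsab1 from 0.565 to 0.0662 FPKM, and Cpa3 to 24.4% of its level in the proliferating control. The 6 megakaryocyte and platelet markers had a median of -0.84, below every random list. The authors' deposited table called 3 of them lower, against 4 lower and 1 higher adjusted over the list alone. With no filter on low values the median was 0 and the list did not stand apart. Plek went from 33.4 to 8.25 FPKM, Gp5 from 19.5 to 5.20 FPKM and Rab27b from 1.75 to 0.578 FPKM. Glucocorticoid-induced genes had a median of -0.35 over 13 genes, below every random list, and of -0.95 over members at 5 FPKM or more, with 3 called lower and 2 higher in the authors' deposited table, against 5 and 3 adjusted over the list alone. Fkbp5 went from 17.2 to 6.90 FPKM and Zfp36l2 from 128 to 52.4 FPKM. The metallothionein Mt2, which is similar in sequence to Mt1 and may share fragments with it, went from 216 to 644 FPKM. No granulocyte, monocyte, lymphocyte, fibroblast, endothelial or hepatocyte marker with 1 FPKM or more was called in the authors' deposited table. Adjusted over the list alone, 1 passed, Trf as higher, at only 0.0364 and 0.128 FPKM. Trf reached 1 FPKM in the knockdown library only, and as the 1 measured gene of its list its p-value was not changed by that adjustment.

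DNA replication (median 0.32 over 26 genes) and mitosis (0.27 over 25 genes) stood above every random list. Ribosome biogenesis (-0.27 over 21 genes) stood below every random list. None of these 3 lists held a call in the authors' deposited table, and 0 genes were called adjusted over the list alone. Cdc6 was at 6.48 and 11.5 FPKM, Ube2c at 37.6 and 58.4 FPKM and Npm1 at 185 and 133 FPKM. The list of unfolded protein and amino acid stress had a median of -0.65 over 14 genes, below every random list. In the authors' deposited table Chac1 was the 1 gene called lower, also adjusted over the list alone, at 2.07 and 0.362 FPKM. The p53 target list (-0.22 over 21 genes) and heat shock genes (-0.21 over 10 genes) stood at percentiles 0.01 and 0.87, with 0 calls in the authors' deposited table and 0 adjusted over the list alone. The heat shock list did not stand apart with the mean, with a pseudocount of 5 or over members at 5 FPKM or more. Lists within the range of random lists were H4K20 methylation and Setd8 turnover (0.05), other histone lysine methyltransferases (-0.0033), autophagy and late maturation (0.15) and interferon-stimulated genes (0.15), with 0 calls in the authors' deposited table and 0 adjusted over the list alone. The autophagy list, at percentile 97.5, stood apart under 5 alternatives, among them an equal upper quartile, the H4K20 list over members at 5 FPKM or more, and the interferon list with no filter on low values. In the second of these 4 the mean had the opposite sign of the median.

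The authors' deposited table called 198 genes changed over the 6 h, 66 higher and 132 lower. Of these, 106 had at least 1 FPKM in a library and 63 at least 5 FPKM. The largest increases among the latter also included Rgs12, at 1.58 and 6.95 FPKM, Cited4, at 26.2 and 71.5 FPKM, Atp1b2, at 29.0 and 72.2 FPKM, Hemgn, at 6.11 and 16.0 FPKM, and the lipid droplet gene Plin2, at 61.7 and 142.0 FPKM. The largest decreases also included Rasd1, at 18.5 and 2.05 FPKM, Parm1, at 11.6 FPKM and 12.7% of that level, Klhl6, at 7.58 and 0.798 FPKM, and Fam198b, at 9.74 and 1.47 FPKM. By size alone, 160 genes had a log2 ratio of 1 or more, 50 higher and 110 lower.

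Both comparisons share the proliferating control library, so chance in that library moves them the same way. Of 11160 genes tested in both, 73 were called in both by the authors' deposited table. Among these, 28 were higher in the knockdown and lower in the maturing control, where independent lists would share 4.48. The reverse held for 11, against 1.79, while 22 were lower in both, against 4.45, and 12 higher in both, against 1.80. In 100 simulations with no effect, run on 3406 genes with the errors of the authors' model, the mean number of shared calls was 0.78, and 1 was observed among those genes. They had at least 5 FPKM in every library, so no simulated value stands for the 73 shared calls, most of them of lower genes. Across the 3406 genes, which are not independent replicates, Pearson's r of the log2 ratios was 0.05 where the simulations gave 0.48. The covariance was 0.0074 against 0.163. The errors of that model were wider than the spread between libraries. For maturation its median SD was 0.45 and the observed robust SD 0.23, so the difference of the covariances gives no estimate of a shared effect. With 1 control library the controls could not be split, and part of the overlap may come from it.

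**Figure D3:**
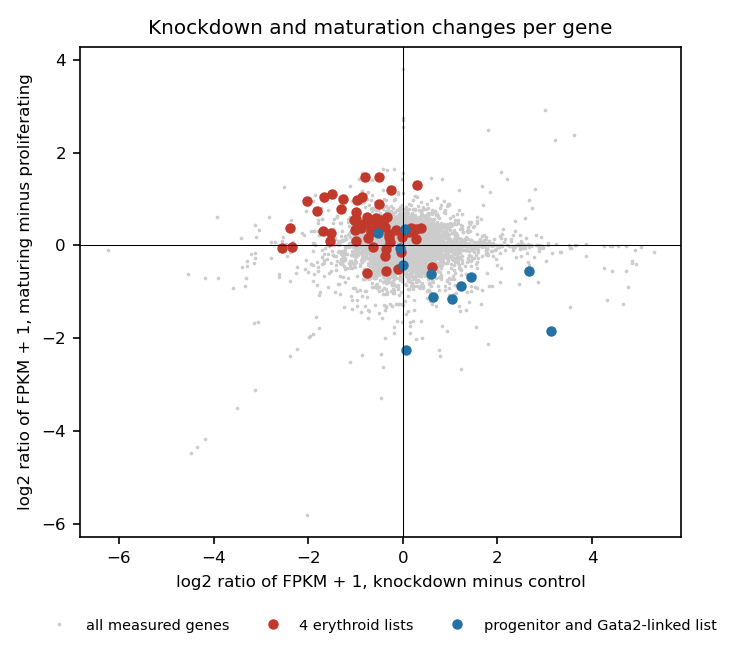
Log2 ratio of FPKM + 1 for knockdown minus control (horizontal) and maturing minus proliferating (vertical), 1 point per measured gene, from 1 library per group. Of the 61 measured genes of the 4 erythroid lists (red), 44 lie at upper left, lower in the knockdown and higher in the maturing control.

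The third comparison of the same table set the proliferating knockdown against the maturing control, which changes both factors together. It was used for 19067 genes, in alphabetical order up to Slc2a13, and the authors' deposited table called 1072 of them, 667 higher and 405 lower in the knockdown.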

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

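Leaving out predicted genes and short RNAs, the alternatives to the overlap of calls and the other bounds and short RNAs for genes near 0 were chosen after seeing the data. The number of knockdown calls, 1056, fell to 559 at 1 FPKM or more, 247 at 5 FPKM or more and 491 with a log2 ratio of 1 or more. The 198 maturation calls fell to 106, 63 and 82 under the same limits, and to 106 at a q below 0.01. Each of these limits removes genes by construction. The count of genes past a size rule, knockdown against control, was 671, and became 222 with a pseudocount of 5 and 381 with a filter at 5 FPKM. The count of genes past a size rule, maturation against proliferation, was 160, and became 51 with a pseudocount of 5, 308 with one of 0.1 and 294 on the TPM scale, where values are larger and the added 1 counts for less. The overlap of 73 calls became 46 at a q below 0.01 and 10 at 5 FPKM or more. The mast cell median in the knockdown, 1.10, was 2.35 with a pseudocount of 0.1, 2.08 on the TPM scale, and 2.87 both over members at 5 FPKM or more and with a filter at 5 FPKM. Some members passed the 5 FPKM limit only through their knockdown value, so 2.87 is partly selected. The same holds for some members at the 1 FPKM limit, and so for 1.10. The MAPK median in maturation, -0.90, was -1.85 with a pseudocount of 0.1 and -1.57 on the TPM scale. With no filter, silent members entered the progenitor list, and its medians became 0.0299 in the knockdown and -0.0475 in maturation. For the same reason the megakaryocyte median in maturation became 0. Under the centred, upper-quartile and TPM scalings, all 16 lists that stood apart in each comparison still did. Without globins the remaining 15 did in each. With the mean, 13 knockdown and 14 maturation lists did, and over members at 5 FPKM or more 14 and 15. Among named genes 162 values moved by more than 1.5 times, under the pseudocounts and the TPM scale only, and no called gene changed sign. Not run, since the maturing knockdown was not analysed here, were the alternatives for both comparisons with that group, for the overlap of knockdown calls between states, for the difference of knockdown effects and for the maturation response in knockdown cells. Leaving out single libraries was not run, with 1 per group. Depth limits low genes most, and calls below 1 FPKM rest on few fragments.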

Other observations

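All tests in this part were chosen after the result was seen, as were the gene names that no rule fixed before the data were examined. Short RNAs left out, 20 genes at 5 FPKM or more in the proliferating control were below 0.2 FPKM in the knockdown, and 25 were the reverse. With bounds of 10 and 0.1 FPKM the numbers were 4 and 7. Genes on in the knockdown included the transporter gene Abcc2, at 0.0247 and 20.2 FPKM, Cd63, listed at 0 and at 13.7 FPKM, and Ddc, at 0.0719 and 11.6 FPKM. The similar genes Cd200r1, Cd200r3 and Cd200r4 on chromosome 16, which can share fragments, were at 5.51, 10.8 and 6.74 FPKM in the knockdown. Genes off in the knockdown included Fabp5 and Fgf13, listed at 0 there and at 8.79 and 7.59 FPKM in the control, and Aldh1a1, at 5.28 and 0.079 FPKM.

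With short RNAs included, 25 of 4999 genes at 5 FPKM or more in the proliferating control were near 0 in the knockdown and 9 in the maturing control, with overlapping exact 95% binomial intervals (from 0.324%, and up to 0.341%). The 20 of the 25 that the authors' deposited table called, each at a q of 0.00661 or less, were those that are not short RNAs. There was 1 such gene in the maturing control, and these intervals did not overlap (0.245% to 0.617%, and up to 0.111%). The call rests on the same difference between single libraries, and genes of 1 library are not independent draws. Chance between any 2 libraries therefore stays open for the 20. It also stays open for the 5 uncalled ones, all short RNAs, against 8 in the maturing control. Loss of chromosome segments spanning neighbouring genes would lower those neighbours by 1 or more on the log2 scale. The nearest measured genes on both sides of the 20 had a median log2 ratio of -0.24 (bootstrap 95% interval -0.72 to -0.09). This argues against such loss as a shared cause for all 20, but a pooled median cannot speak for a single locus. Of the 40 neighbours, 8 were near 0 themselves. On chromosome 15 they lay between 74551663 and 74790335, with a predicted gene (7.83 and 0.00716 FPKM), Gml, Hemt1 and Ly6e. On chromosome 2 they lay with Slc28a2 (8.17 and 0.0301 FPKM) and a similar predicted gene. Loss of a segment stays open at these places. A line or clone that differed beforehand cannot be told apart from an effect of the knockdown, with 1 knockdown library analysed.

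Red cell lists had lower medians and the mast cell list a higher one in the knockdown. A lower share of erythroid cells would lower alike those genes that only these cells make. The median of the membrane list lay 1.06 above that of the globins on the log2 scale (bootstrap 95% interval 0.22 to 1.36). The lists were not limited to such genes, and some globin rows share copies, so the gap does not decide on a changed share of cells. If dilution alone lowered the globins, 65.5% of the RNA would need to come from other cells. That share was taken from the median ratio of FPKM + 1, the value of Hbb-bh1, which understates the fall. Without the added 1, Hbb-bh1 in the knockdown was at 29.3% of the control. Mature mast cells or basophils mixed into the culture stay open: the other 9 granule protease and IgE receptor genes of the list had a median of 3.80% of Tpsab1 in the knockdown library, with a bootstrap 95% interval of 0.0147% to 52.1% that holds the 10% set as the least such cells would bring. The median rests on which genes are counted: without Gzmb it was 5.81% over 8 genes, and without Cma1, Ms4a2 and Tpsb2 as well, a choice tried first that would have argued against such cells, it was 0.84% over 5.

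The medians of the erythroid lists were lower in the knockdown and higher in the maturing control. Chance in the shared control library alone would move both the same way and so cannot give opposite signs; the covariance of the log2 ratios over 73 genes of the erythroid and progenitor lists, -0.36 (bootstrap 95% interval -0.61 to -0.15), restates this on lists seen to show it, while over 3406 genes it was 0.0074. A scaling factor common to all genes would move random matched lists alike, yet all 4 erythroid lists stood apart from them in both comparisons (3 with the mean). Chance in the knockdown or the maturing library was not tested, and a differing line or clone stays open. That a lower Setd8 level may hold proliferating erythroblasts at an earlier state is a hypothesis without a test of its own. Some lists stood apart with medians of the same sign in both comparisons. These were ribosome biogenesis (-0.32 and -0.27), unfolded protein and amino acid stress (-0.53 and -0.65) and the p53 target list (-0.34 and -0.22). Heat shock genes (-0.36 and -0.21) and erythropoietin and STAT5 targets (0.29 and 0.48) did so too. Chance in the shared control library also gives the same sign, so these lists count neither for nor against the hypothesis.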
